A study of Oryza sativa with 6 samples.

How the data were processed

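RNA was extracted with Trizol from 4-leaf rice seedlings grown at 28 °C without treatment, and biotin-labelled cRNA made from 6 µg of total RNA was hybridised to 1-colour Affymetrix rice arrays. The series holds 6 arrays: 2 biological replicates each of wild type, OsUBA overexpression and OsUBA RNAi. The authors deposited a table of log2 expression values, 57381 probe sets by 6 arrays, and the values were used as deposited. The submitters' processing notes name RMA without a version. The deposited values hold 329 to 614 exact zeros per array and distributions that differ slightly between arrays, which is unlike the usual RMA output, so the way probe values were summarised is open. The table has no detection calls, and signal over background was not used here.

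Control probe sets (123 hybridisation and RNA controls and 64 reporter probe sets) were left out of the fits of the gene comparisons. The 64 reporter probe sets were added back to the kept probe sets in a separate limma fit and adjusted together with them; its alternatives added back only the 2 bright ones. Of 57194 other probe sets, 22436 map to 1 gene in the annotation given for the array, 95 to several and 34663 to no listed gene. A probe set was kept if at least 2 of the 6 arrays had a log2 value of 5 or more, which kept 40466 probe sets, with 16691 genes among them, and left out 16728. Where the mean of a group lay under this floor of log2 5, a named change against it was counted from the floor and is given as a lower bound, with none given where both groups lay under it. Tests and list medians used the values as deposited. Gene names came from a rice RefSeq gene table, in which all 17905 gene identifiers were found; 2315 genes have a name other than a clone or locus number. No genome positions were used.

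Each comparison was tested with limma 3.58.1 in R 4.3.3, with 1 model of the 3 group means over all 6 arrays (3 residual degrees of freedom), two-sided moderated tests without an intensity trend, and Benjamini-Hochberg adjustment over all kept probe sets at a threshold of 0.05. This test, the filter, the alternatives other than those named below as chosen later, the rule for named genes and 35 gene lists were set before the data were examined. The same fit with an intensity trend was one of the alternatives. After the fit without a trend had called 5 probe sets or fewer, its counts were reported as results of their own. The typical spread between replicates fell with brightness, from a median SD of 1.02 under a mean log2 value of 6 to 0.166 at 12 and over. Estimated prior degrees of freedom were 1.53 without a trend and 4.70 with it.

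Gene lists were tested with camera (limma) at a preset correlation of 0.01, with 1 probe set per gene, the one with the highest mean, and Benjamini-Hochberg adjustment over the lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance one way, and does not compare them with other genes. The annotation tables hold names but no descriptions, so 19 of the 35 fixed lists had no measured gene and 9 had 5 or more. A further 36 lists, written from gene names and synonyms after the annotation tables and control probe sets had been seen but before any gene's values, brought the number tested to 45. Of the lists with calls, jasmonate and the shorter auxin list were fixed and the others added. With an estimated correlation 0 of 45 lists passed in each comparison, at smallest adjusted p values of 0.887, 0.5998 and 0.675. That form of the test rests on the 3 residual degrees of freedom and has little power. Its high p values therefore do not argue against a list, and the list calls rest on the preset correlation.

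The rule for named genes took, per comparison, the 12 largest rises and 12 largest falls among called probe sets with 1 gene and non-overlapping groups, 1 probe set per gene. If none passed, it took the 5 with the smallest p in each direction. It also took up to 4 called members of each list and up to 10 genes called in both transgenic groups in each direction. Added later, the same rule was applied to the intensity-trend fit for genes with a name other than a clone or locus number. List members were then taken if they passed adjusted over the list alone, and genes called in both transgenic groups were taken from the intensity-trend fit.

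Alternatives were other filters, quantile normalisation, centring each array on its median, array weights, a fit of only the 4 arrays compared, replicate number as a block, averaging the probe sets of a gene, a 2-fold limit, and leaving out each array in turn. Where an array is left out, the lone array of its group is assumed to vary like the other groups. With 2 arrays a group, regrouping the arrays was not used as a test. The overlap of calls in both transgenic groups was compared with independent lists only. The correlation, covariance and share of equal signs of their log2 changes were compared with 100 simulations of unchanged groups sharing the wild-type arrays. Quantile normalisation and centring moved the median log2 change of all probe sets by less than 0.1.

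The fits were tested on simulated data with 40466 probe sets and the fitted spreads, with 50 probe sets changed at each of 4 sizes. Without a trend, 0% of changes of 1 or 2 on the log2 scale were recovered, 30 to 32% of changes of 4 and 52 to 66% of changes of 6; 4.65 to 12.5% of calls were false. With a trend these were 0 to 2%, 18 to 20%, 46 to 50% and 60 to 64%, with 0 to 3.03% of calls false. A simulated list shifted by -0.8 was recovered in 20 of 20 draws. Its genes were drawn independently of each other and all shifted alike, so this does not test lists of correlated genes.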

Results

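Transcript levels were measured in untreated rice seedlings (Oryza sativa) at the 4-leaf stage, grown at 28 °C, on 1-colour Affymetrix rice arrays. The 6 arrays fall into 3 groups of 2 biological replicates: wild type (cultivar Nipponbare), plants overexpressing OsUBA, and plants in which OsUBA was targeted by RNA interference (RNAi), a way to lower a transcript through matching double-stranded RNA. The labels name no transformed control group without an OsUBA construct. Changes against wild type can therefore not be told apart from effects of transformation. The median log2 value of an array ranged from 5.67 to 5.92, and 34231 to 36277 probe sets of an array reached a log2 value of 5. The 2 arrays of a group correlated at r = 0.913, 0.916 and 0.913 across probe sets (wild type, overexpression, RNAi), and arrays of different groups at 0.852 to 0.911. Probe sets are not independent replicates, and the small number of arrays limits the precision of every value. Group levels are log2 means ± SD (n = 2), and log2 changes are given ± SE. Genes carry the symbol and locus identifier of the annotation; genome positions were not used here. Adjusted p values are Benjamini-Hochberg values from limma. A limma fit whose prior spread follows brightness is called the intensity-trend fit; it was planned as an alternative, and its counts are reported as results of their own because the planned fit called 5 probe sets or fewer. In every gene described as risen or fallen by that fit, both arrays of one group lay above both arrays of the other.

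The comparison of overexpression with wild type asks which transcripts change in plants made to overexpress OsUBA. LAC20 (LOC4351006), a laccase, rose in the intensity-trend fit, from log2 6.67 ± 0.30 in wild type to 10.62 ± 0.52 in overexpression, or 15.5-fold (log2 change 3.95 ± 0.44, adjusted p = 0.0171). SUS1 (LOC4333062), a sucrose synthase, rose in the same fit from 7.72 ± 0.31 to 11.68 ± 1.15 (adjusted p = 0.0309), and UGD3 (LOC4334169), a UDP-glucose dehydrogenase, from 9.88 ± 0.43 to 12.16 ± 0.03 (adjusted p = 0.0141). Another probe set of SUS1 did not pass (log2 change 3.47, adjusted p = 0.0664). The beta-tubulin gene TUB4 (LOC4327550) rose 4.32-fold (adjusted p = 0.0491) and GT43A (LOC4337665), of a glycosyltransferase family that acts in xylan synthesis, 2.75-fold (adjusted p = 0.0485). Other probe sets of TUB4 did not pass (log2 changes 2.41 and 0.93, intensity-trend adjusted p = 0.463 and 0.571). Among genes with a name, the largest rises were those of AT15 (LOC4347960), 26.4-fold (adjusted p = 0.0077), and HOS66 (LOC4331449), 22.96-fold (adjusted p = 0.0128). Without overexpression replicates 1 and 2 the fold of HOS66 was 15.2 and 34.7 and that of SUS1 8.91 and 27.5.

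The other named rises were those of ADIPOR1 (LOC4341641, 8.06-fold), METK3 (LOC4325163, 6.88-fold), an S-adenosylmethionine synthase, ZIP5 (LOC4339082, 5.40-fold), of a zinc transporter family, ACLA-2 (LOC9272295, 4.73-fold), an ATP-citrate lyase subunit, and ta4 (LOC4329846, 4.24-fold). Their adjusted p values lay between 0.00319 and 0.0416. In all, the intensity-trend fit called 144 probe sets, 140 higher and 4 lower in overexpression; 104 genes with a locus identifier were higher and 0 lower (limma; 3859 probe sets had an unadjusted p under 0.05). The planned fit called 0 of 40466 probe sets, with 3301 at an unadjusted p under 0.05 against 2023 expected by chance; it called 1 with a filter on the mean of all arrays, 16 with a filter at log2 6 and 6 with averaged probe sets. The smallest adjusted p of the planned fit was 0.112, for LOC4332782, at log2 5.99 ± 0.22 in wild type and 12.37 ± 0.22 in overexpression. LOC4348710, LOC4336565, LOC4350075 and LOC4331398 had the next smallest p among higher values. LOC4350075 had a log2 change of 3.91, and LOC4348710, LOC4336565 and LOC4331398 were at least 1.29-fold, 53.5-fold and 97.1-fold higher, counted from the filter's floor of log2 5. Among lower values these were LOC4348658, LOC4350095, LOC4333720, PIP2-8 (LOC4334873), an aquaporin, and LOC4342721, with adjusted p values of 0.138 to 0.190. LOC4348658 averaged under the floor in both groups, and the other 4 were at least 1.68-fold, 1.53-fold, 1.11-fold and 2.13-fold lower, counted from the floor. None of these 10 passed in the planned fit, and other probe sets of LOC4333720 and LOC4342721 had log2 changes of 0.16 and -0.67. The intensity-trend fit did call LOC4332782, LOC4336565, LOC4350075 and LOC4331398. The count of 144 became 20 and 28 without wild-type replicates 1 and 2, 0 and 74 without overexpression replicates 1 and 2, and 223 without RNAi replicate 1. Of 21 named calls of the intensity-trend fit in this comparison, 0 remained past the threshold without overexpression replicate 1, 3 without wild-type replicate 1, 6 without wild-type replicate 2 and 8 without overexpression replicate 2.

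Of 45 gene lists, 2 passed the camera set test between overexpression and wild type. Kinesins, the motor proteins of microtubules, were higher as a list (adjusted p = 0.0181; 22 of 30 genes positive, median log2 change 0.51). Genes of diterpenoid phytoalexin synthesis, antimicrobial compounds of rice, were lower as a list (adjusted p = 0.0181; 13 of 16 genes negative, median -0.98). That median was not counted from the floor of log2 5. KSL5, KSL7, CPS4 and CYP76M5 of this list averaged under the floor in overexpression, and OsMAS did so in both groups. Both calls were lost with an estimated correlation (adjusted p = 0.887 with an estimated correlation for each). In both lists 0 genes passed adjusted over the list alone, and 0 passed over all probe sets. The kinesin call ended without wild-type replicate 2 (adjusted p = 0.422) and both ended without overexpression replicate 1 (adjusted p = 0.317 each). The number of lists past the threshold was 4 without wild-type replicate 1 and 0 without overexpression replicate 1. The diterpenoid call also ended when the probe sets of each gene were averaged (adjusted p = 0.0669). The list of cellulose synthases, cellulose synthase-like genes and xyloglucan endotransglucosylases missed the threshold, with 23 of 32 genes positive and a median of 0.38 (adjusted p = 0.0510).

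The comparison of RNAi with wild type asks which transcripts change when OsUBA is targeted. Cellulose synthases and related cell wall genes were lower in RNAi as a list. Of 32 genes in the cellulose synthase list, 13 fell, 0 rose and 19 did not pass, adjusted over the list alone, and 25 were negative (median log2 change -1.02; camera adjusted p = 6.28e-09, but adjusted p = 0.5998 with an estimated correlation). CESA4 (LOC4324625), a cellulose synthase of secondary walls, stood at 11.74 ± 0.03 in wild type and 7.66 ± 1.03 in RNAi, a 17.0-fold fall (intensity-trend adjusted p = 0.0120) that was 28.2-fold and 10.3-fold without RNAi replicates 1 and 2. CESA1 (LOC4337958) went from 12.48 ± 0.04 to 9.90 ± 0.16 (adjusted p = 0.00236), CESA8 (LOC4342699) from 12.03 ± 0.11 to 9.65 ± 0.56 (adjusted p = 0.0148) and CESA5 (LOC4334710) from 9.65 ± 0.10 to 7.72 ± 0.15 (adjusted p = 0.0233), all in the intensity-trend fit. Another probe set of CESA1 did not pass between RNAi and wild type (log2 change -1.97, intensity-trend adjusted p = 0.0656).

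Phenylpropanoid and lignin genes were also lower in RNAi, with 5 of 27 fallen, 0 risen and 22 not past, adjusted over the list alone (camera adjusted p = 0.000417, but adjusted p = 0.5998 with an estimated correlation; median -0.68). The laccase LAC4 (LOC4327500) had the largest fall among genes with a name, from 10.83 ± 0.69 to 4.73 ± 1.20, at least 56.7-fold counted from the floor of log2 5 (intensity-trend adjusted p = 0.00644). LAC20 fell from 6.67 ± 0.30 to 3.18 ± 0.45, at least 3.19-fold (adjusted p = 0.0204). 4CL3 (LOC4328485), a 4-coumarate:CoA ligase, fell by 2.14 on the log2 scale (adjusted p = 0.00359), and CAD2 (LOC4328552), a cinnamyl alcohol dehydrogenase, fell by 1.85 (adjusted p = 0.0218). Of 30 kinesins, 7 fell, 0 rose and 23 did not pass, adjusted over the list alone (camera adjusted p = 0.000417, but adjusted p = 0.5998 with an estimated correlation; median -0.56). KIN14H, at 10.48 ± 0.09 in wild type and 6.77 ± 1.39 in RNAi, and KIN5A (LOC9268593), at 7.89 ± 0.46 and 5.18 ± 0.64, passed in the intensity-trend fit (adjusted p = 0.0320 and 0.0430). The fold of KIN14H was 25.8 and 6.63 without RNAi replicates 1 and 2. KIN12C (LOC4333349) and KIN14C (LOC4326167) passed in the list alone only (adjusted p = 0.0207 each; intensity-trend adjusted p = 0.309 and 0.0735). KIN12C averaged 5.46 in wild type and 2.57 in RNAi, at least 1.38-fold lower counted from the floor, and KIN14C had a log2 change of -1.68 ± 0.25.

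Auxin genes, here Aux/IAA repressors of auxin signalling and SAUR39, were lower in RNAi: 5 of 27 fell, 0 rose and 22 did not pass, adjusted over the list alone (camera adjusted p = 1.89e-05, but adjusted p = 0.5998 with an estimated correlation; median -0.85). IAA30 (LOC4352721) went from 9.37 ± 0.07 to 6.45 ± 0.88 and IAA21 (LOC4340939) from 11.79 ± 0.05 to 10.23 ± 0.09 (intensity-trend adjusted p = 0.0338 and 0.0324). The fold of IAA30 was 11.7 and 4.93 without RNAi replicates 1 and 2. IAA8 (LOC4330571) and IAA24 (LOC4342573) passed in the list alone only (adjusted p = 0.0462 each; log2 changes -1.51 and -1.49). A broader auxin list of 57 genes that shares members with it was lower as well (camera adjusted p = 0.00364, but adjusted p = 0.5998 with an estimated correlation; 0 of its genes passed adjusted over the list alone), and that call ended without RNAi replicate 2 (adjusted p = 0.0655).

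Jasmonate genes were higher in RNAi, with 4 of 16 risen, 0 fallen and 12 not past, adjusted over the list alone (camera adjusted p = 0.00662, but adjusted p = 0.680 with an estimated correlation; median 0.49). The 4 are JAZ genes, repressors of jasmonate signalling that jasmonate itself induces. JAZ9 (LOC4331832) stood at 5.80 ± 1.004 in wild type and 9.38 ± 0.07 in RNAi, JAZ12 (LOC4348533) at 9.67 ± 0.16 and 12.33 ± 0.14, and JAZ13 (LOC4348531) at 6.22 ± 0.06 and 9.82 ± 0.66 (intensity-trend adjusted p = 0.0245, 0.0195 and 0.0465). The fold of JAZ9 was 19.5 and 7.31 without wild-type replicates 1 and 2. JAZ11 (LOC4331833) passed in the list alone only (adjusted p = 0.0310, log2 change 2.49 ± 0.55). The jasmonate call ended without wild-type replicate 2 (adjusted p = 0.127) and without RNAi replicate 2 (adjusted p = 0.263). Protein phosphatases 2C, a family that includes negative regulators of abscisic acid signalling, were higher as a list, with 3 of 52 risen, 0 fallen and 49 not past, adjusted over the list alone (camera adjusted p = 0.0126, but adjusted p = 0.5998 with an estimated correlation; median 0.13). PP2C68 rose 3.39-fold and OsPP2C09 (LOC4327465) 3.05-fold (intensity-trend adjusted p = 0.0332 and 0.0121), and OsPP2C08 (LOC4324182) passed in the list alone only (adjusted p = 0.0425, 2.43-fold). The PP2C68 call was lost whichever array was left out, at folds of 3.11 to 3.68. Heat shock factors were higher as a list, with 18 of 21 positive and 0 past adjusted over the list alone (camera adjusted p = 0.00440, but adjusted p = 0.5998 with an estimated correlation; median 0.32). Without wild-type replicate 2 the phosphatase and heat shock factor calls ended (adjusted p = 0.235 and 0.126), and 5 of the 8 list calls of this comparison were left.

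**Figure D1:**
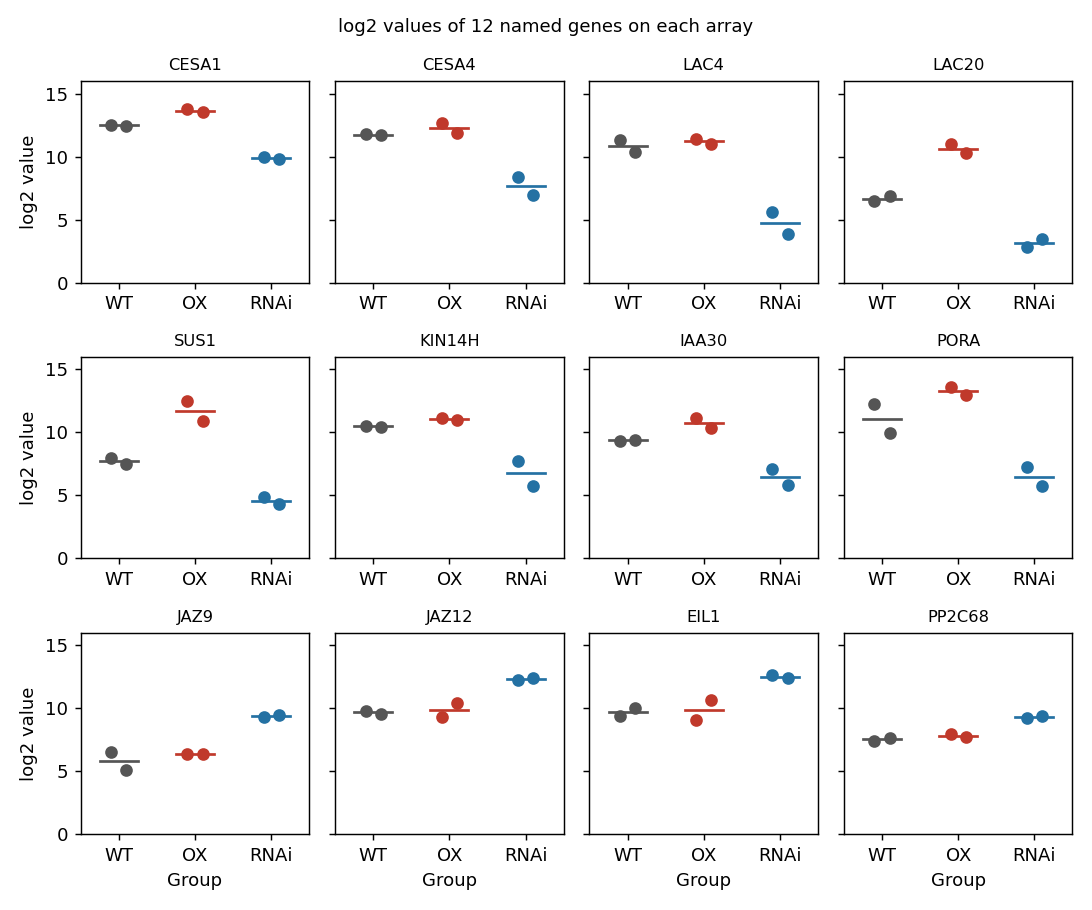
Log2 values of 12 named genes on each of the 6 arrays, with a dot per array and a line at the mean of each group of 2 (WT, wild type; OX, overexpression). In RNAi, LAC4 averaged 4.73 against 10.83 in wild type and CESA1 9.90 against 12.48, while JAZ12 averaged 12.33 against 9.67.

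Outside these lists, PORA (LOC4337415), a protochlorophyllide reductase of chlorophyll synthesis, fell 24.3-fold between wild type and RNAi in the intensity-trend fit (11.10 ± 1.61 against 6.50 ± 1.05, adjusted p = 0.0428). That fold was 11.06 and 53.5 without wild-type replicates 1 and 2 and 40.7 and 14.5 without RNAi replicates 1 and 2. Of the 6 fits that leave out 1 array, PORA passed only in the one without RNAi replicate 1 (adjusted p = 0.0188; 0.0638 to 0.218 in the others). Other falls there were those of ta4 (10.3-fold), the beta-glucosidases BGLU10 (LOC4336142, 8.97-fold) and BGLU3 (LOC4327593, 8.66-fold), SUS1 (at least 6.57-fold, counted from the floor of log2 5), EXPB3 (LOC4349349, 7.25-fold), a beta-expansin that loosens cell walls, and CYP734A6 (LOC4325222, 6.84-fold). Without RNAi replicates 1 and 2 the fold of EXPB3 was 11.6 and 4.51, and without RNAi replicate 2 that of BGLU10 was 5.45. Other probe sets of BGLU10 had log2 changes of 0.78, opposite in sign, and -5.35 (adjusted p = 0.447 and 0.146), and another of SUS1 had -1.18 (adjusted p = 0.518). Rises were those of EIL1 (LOC4332697, 6.996-fold), a transcription factor of ethylene signalling, YSL9 (LOC4336545, 3.17-fold), of a metal-chelate transporter family, PDIL1-1 (LOC4350002, 2.78-fold), a protein disulfide isomerase, CIPK29 (LOC4344285, 2.46-fold), a protein kinase, and Hox22 (LOC4336542, 2.35-fold), a homeodomain factor. The calls of PDIL1-1, CIPK29 and Hox22 were lost whichever array was left out, at folds of 2.14 to 3.62, 2.23 to 2.70 and 2.08 to 2.65. PDIL1-1 stood as high in overexpression (12.10 and 12.14) as in RNAi (12.04 and 12.19). The planned fit called 1 probe set, that of LOC4324833, a gene with no name in the annotation, which fell from 13.69 ± 0.16 to 5.81 ± 0.03 (235-fold, log2 change -7.88 ± 0.21, adjusted p = 0.0343). That fit had 3720 probe sets at an unadjusted p under 0.05 against 2023 expected by chance. Its count was 0 with no filter, 18 with a filter on the mean of all arrays, 20 with a filter at log2 6, 4 with averaged probe sets and 0 with only the 4 arrays compared. The intensity-trend fit called 313 probe sets, 77 higher and 236 lower in RNAi.

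In the planned fit LOC4324833 no longer passed without any 1 of the 6 arrays, which leaves 2 residual degrees of freedom, while its log2 change stayed between -7.99 and -7.77. Its adjusted p was 0.257 and 0.278 without wild-type replicates 1 and 2, 0.263 without either overexpression replicate, and 0.195 and 0.288 without RNAi replicates 1 and 2. The count of 313 became 19 and 16 without wild-type replicates 1 and 2, 132 and 147 without overexpression replicates 1 and 2, and 716 and 205 without RNAi replicates 1 and 2. Of 39 named calls of the intensity-trend fit between RNAi and wild type, only CESA1 passed in all 6 of these fits. Past the threshold were 3 and 1 without wild-type replicates 1 and 2, 21 and 22 without overexpression replicates 1 and 2, and 33 and 16 without RNAi replicates 1 and 2.

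The comparison of overexpression with RNAi sets the opposite manipulations of OsUBA against each other and gave the most probe set calls of the 3 comparisons in both fits. The 2 groups also differed in a reporter probe set, at log2 13.43 ± 0.30 in RNAi and 4.34 ± 1.06 in overexpression. Differences between them can therefore not be ascribed to OsUBA alone. Over all probe sets the planned fit called only probe sets without a gene name, so here too no member of a list passed it. Cell wall genes were higher in overexpression: of 32 genes in the cellulose synthase list, 16 were higher, 1 was lower and 15 did not pass, adjusted over the list alone (camera adjusted p = 3.17e-07, but adjusted p = 0.675 with an estimated correlation; median 1.02). CESA1 stood at 13.63 ± 0.18 in overexpression and 9.90 ± 0.16 in RNAi, a 13.3-fold difference, CESA5 differed 12.2-fold, CESA8 14.4-fold and CSLF6 (LOC4344719), which makes mixed-linkage glucan, 13.0-fold. Their intensity-trend adjusted p values ran from 0.000165 to 0.000998. Another probe set of CSLF6 gave a log2 change of 0.83 (adjusted p = 0.751). The lower member, past in the list alone only, was CSLF7 (LOC4348365), named here after its values were seen, at 2.63 ± 1.20 in overexpression and 5.35 ± 0.19 in RNAi, at least 1.28-fold lower counted from the floor of log2 5. CSLF8 (LOC4343552) was at least 9.53-fold higher in overexpression in the intensity-trend fit, a bound of 5.34-fold and 17.0-fold without overexpression replicates 1 and 2. The CSLF8 call was lost in those fits (adjusted p = 0.334 and 0.0873) and without RNAi replicate 2 (adjusted p = 0.0547). CESA7 (LOC4348853) averaged 12.55 ± 0.50 in overexpression and 7.12 ± 2.52 in RNAi (log2 change 5.43 ± 0.95, intensity-trend adjusted p = 0.0215). That change was 7.22 without RNAi replicate 1 and 3.65 without RNAi replicate 2. The CESA7 call was lost without wild-type replicates 1 and 2 (adjusted p = 0.0655 and 0.0646) and without overexpression replicates 1 and 2 (adjusted p = 0.186 and 0.0779).

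Of 27 phenylpropanoid and lignin genes, 7 were higher in overexpression than in RNAi, 0 lower and 20 did not pass, adjusted over the list alone (camera adjusted p = 0.00243, but adjusted p = 0.675 with an estimated correlation; median 0.98). LAC20 differed at least 49.2-fold (10.62 ± 0.52 against 3.18 ± 0.45) and LAC4 at least 74.4-fold, both counted from the floor of log2 5, with intensity-trend adjusted p values of 0.000425 and 0.00118. 4CL3 and CAD2 were 4.15-fold and 5.30-fold higher (adjusted p = 0.00113 and 0.00226). Of 30 kinesins, 11 were higher, 0 lower and 19 did not pass (camera adjusted p = 1.22e-05, but adjusted p = 0.675 with an estimated correlation; median 1.02), among them KIN14F (LOC4332578, at least 8.57-fold), KIN7K (LOC4349100, 9.81-fold), KIN5A (8.84-fold) and KIN14C (6.46-fold). The bound for KIN14F was 5.25-fold and 13.99-fold without overexpression replicates 1 and 2. Of 27 auxin genes, 10 were higher, 0 lower and 17 did not pass (camera adjusted p = 0.000372, but adjusted p = 0.675 with an estimated correlation; median 0.89). IAA30 differed 19.3-fold, IAA21 7.44-fold, IAA12 (LOC4333512) 4.82-fold and IAA31 (LOC4352722) 4.34-fold. The IAA12 call was lost whichever array was left out, and its fold was 3.89 and 5.97 without overexpression replicates 1 and 2. The fold of IAA30 was 29.8 and 12.5 without RNAi replicates 1 and 2. The broader auxin list was higher too, with 2 of 57 past in the list alone (camera adjusted p = 0.0261, but adjusted p = 0.675 with an estimated correlation). Its call ended without overexpression replicate 2 (adjusted p = 0.145) and without RNAi replicate 2 (adjusted p = 0.158).

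Jasmonate genes were lower in overexpression than in RNAi, with 5 of 16 lower, 0 higher and 11 not past, adjusted over the list alone (camera adjusted p = 0.00637, but adjusted p = 0.698 with an estimated correlation; median -0.85). The 5 were JAZ9, JAZ10 (LOC4331834), JAZ11, JAZ12 and JAZ13, with log2 changes of -3.01, -2.22, -2.10, -2.47 and -2.98 and intensity-trend adjusted p values of 0.00707 to 0.0405. As folds, JAZ10 was 2.90 and 7.44 and JAZ13 4.21 and 14.7 without overexpression replicates 1 and 2, and JAZ11 6.63 and 2.79 without RNAi replicates 1 and 2. Without RNAi replicate 2 the list call ended (adjusted p = 0.0863). Protein phosphatases 2C were lower as a list, with 36 of 52 negative and 0 past adjusted over the list alone (camera adjusted p = 0.0407, but adjusted p = 0.675 with an estimated correlation; median -0.23). That call ended without wild-type replicate 1 or 2 (adjusted p = 0.0594 each), without overexpression replicate 1 (adjusted p = 0.0987), without RNAi replicate 2 (adjusted p = 0.0722) and with averaged probe sets (adjusted p = 0.0997).

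**Figure D2:**
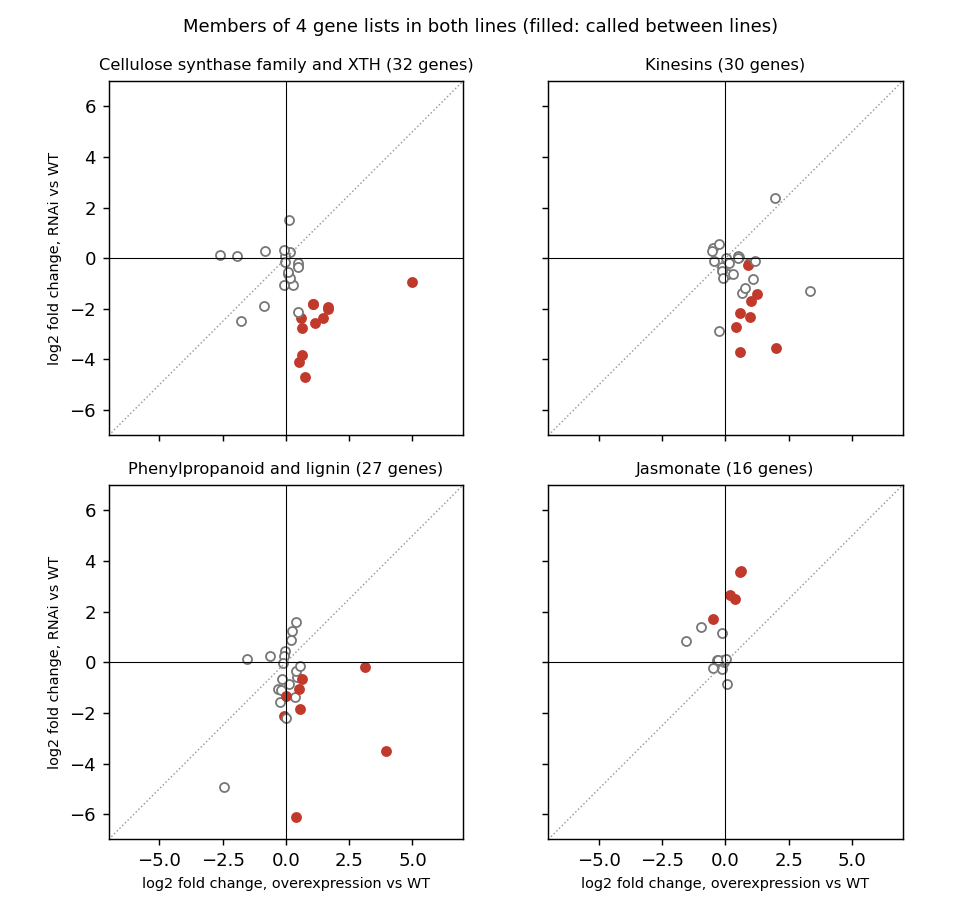
Members of 4 gene lists, each dot a gene, with the log2 change of overexpression against wild type on the x axis and of RNAi against wild type on the y axis; filled dots passed between overexpression and RNAi in the intensity-trend fit. Filled dots of the cellulose synthase, kinesin and phenylpropanoid lists lie below 0 on the y axis, where these lists had medians of -1.02, -0.56 and -0.68, and those of the jasmonate list above 0.

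Single genes that were higher in overexpression than in RNAi in the intensity-trend fit GLP1 (LOC4345763), a germin-like protein (log2 change 7.51 ± 1.17), PORA (6.78 ± 0.73), HOS66 (5.72 ± 0.47) and ta4 (5.45 ± 0.23). Counted from the floor of log2 5, SUS1 was at least 102.8-fold higher, AT15 at least 82.6-fold and PRX74 (LOC4339222), a peroxidase, at least 17.3-fold; they averaged 4.59, 4.54 and 0.52 in RNAi. Another probe set of SUS1 had a smaller log2 change of 4.65 (adjusted p = 0.00520). Without overexpression replicates 1 and 2 the bounds were 58.5-fold and 180.4-fold for SUS1 and 5.69-fold and 52.5-fold for PRX74, and the folds were 65.5 and 510.4 for GLP1 and 34.8 and 79.6 for HOS66. The PRX74 call was lost in those fits (adjusted p = 0.495 and 0.113) and without RNAi replicate 2 (adjusted p = 0.103). The fold of PORA was 184.3 and 65.9 without RNAi replicates 1 and 2. Lower were CPS2 (LOC9266189), a copalyl diphosphate synthase (log2 change -4.03 ± 0.42), CYP71Z6 (LOC4329725, -3.28 ± 0.66) and CYP701A8 (LOC4341343, -2.94 ± 0.52), P450 enzymes of diterpenoid metabolism, EIL1 (-2.63 ± 0.47), 4CLL7 (LOC4342925, -2.23 ± 0.34), GLT2 (LOC4339561, -1.98 ± 0.32) and WRKY71 (LOC4328512, -1.97 ± 0.39), a WRKY transcription factor. As folds without overexpression replicates 1 and 2, CYP71Z6 was 5.27 and 17.99, EIL1 3.59 and 10.7 and WRKY71 2.58 and 5.94; CYP701A8 was 12.7 and 4.65 without RNAi replicates 1 and 2. Diterpenoid phytoalexin genes as a list missed the threshold between overexpression and RNAi, with 11 of 16 negative and 3 lower adjusted over the list alone (median -1.01, camera adjusted p = 0.105, and adjusted p = 0.742 with an estimated correlation). The intensity-trend fit called 1725 probe sets, 1339 higher and 386 lower in overexpression.

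The planned fit called 5 probe sets between overexpression and RNAi, all higher in overexpression, with 5957 at an unadjusted p under 0.05 against 2023 expected by chance. They were LOC4324833 (395-fold, adjusted p = 0.0228), LOC4338023 (at least 379-fold, counted from the floor of log2 5), LOC4332782 (93.8-fold), LOC4329978 (81.1-fold) and a probe set with no gene listed (at least 55.2-fold, counted from the floor), the last 4 at an adjusted p of 0.0384. The count was 449 with a filter on the mean of all arrays, 593 with a filter at log2 6, 480 with averaged probe sets, 94 with array weights, 11 and 8 under quantile normalisation and centring, and 0 with no filter or only the 4 arrays compared. The 5 also became 0 without any 1 of the 6 arrays, with 2 residual degrees of freedom left, while the log2 change of LOC4324833 stayed between 8.57 and 8.68. The count of 1725 became 276 and 1063 without overexpression replicates 1 and 2 and 927 without RNAi replicate 2. Of 37 named calls of the intensity-trend fit between overexpression and RNAi, 16 passed in all 6 fits that leave out 1 array: CESA1, CESA5, CESA8, CSLF6, LAC4, LAC20, 4CL3, CAD2, SUS1, AT15, HOS66, ta4, IAA21, IAA30, JAZ12 and CPS2. Without wild-type replicate 1 or 2, 29 of the 37 passed; without overexpression replicates 1 and 2, 16 and 30; without RNAi replicates 1 and 2, 32 and 25.

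Overexpression and RNAi were also compared with each other through their changes against wild type. In the intensity-trend fit, 22 probe sets rose in overexpression and fell in RNAi, where independent lists would share 0.816. The reverse held for 0, where independent lists would share 0.00761. Only 4 probe sets were called lower in overexpression, so that 0 carries little information. Among the 22 were LAC20, SUS1, ta4, TUB4, LOC4338023, LOC4330925, LOC4329978, LOC4330177, LOC4327914 and LOC4326149. LOC4338023 stood at 8.85 ± 0.16 in wild type, 13.57 ± 0.54 in overexpression and 4.52 ± 0.30 in RNAi, and TUB4 at 10.28 ± 0.03, 12.39 ± 0.72 and 7.84 ± 0.05. A further probe set of TUB4 gave a log2 change of 1.92 between wild type and RNAi (adjusted p = 0.509), opposite in sign, and a further probe set of SUS1 did not pass in either comparison. In both groups of transgenic plants 14 probe sets rose, where independent lists would share 0.266, and 2 fell, where they would share 0.0233. Those that rose included LOC4335304, LOC4350075 and LOC9267168; LOC4350075 stood at 6.28 ± 0.08 in wild type, 10.19 ± 0.18 in overexpression and 9.65 ± 0.21 in RNAi. Other probe sets of LOC9267168 did not pass (smallest adjusted p = 0.161).

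The planned fit called 0 probe sets in both comparisons with wild type (limma; 3301 and 3720 at an unadjusted p under 0.05). Both comparisons use the same wild-type arrays, so an overlap in the same direction is partly built in. The values for independent lists do not allow for this. Opposite calls numbered 1 and 2 without wild-type replicates 1 and 2, 0 and 7 without overexpression replicates 1 and 2, and 61 without RNAi replicate 1. Calls in the same direction, 16 in all, numbered 6 and 4 without wild-type replicates 1 and 2 and 0 and 7 without overexpression replicates 1 and 2. Across probe sets the log2 changes of overexpression and RNAi correlated at r = 0.273, and 55.6% had the same sign; unchanged groups that share the wild-type arrays gave 0.499 and 66.6% in simulation. The correlation was 0.439 and 0.495 without wild-type replicates 1 and 2, where simulated unchanged groups gave 0.665 and 0.667.

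No probe set was annotated with the name OsUBA or UBA, so the level of the targeted transcript was not analysed here. RAD23 (LOC4347014), a ubiquitin receptor and the one measured gene of the fixed list of proteins with ubiquitin-associated domains, did not pass. Its brightest probe set stood at 10.81 ± 0.36 in wild type, 10.51 ± 0.06 in overexpression and 10.61 ± 0.23 in RNAi (adjusted p = 0.796, 0.876 and 0.889 for overexpression against wild type, RNAi against wild type and overexpression against RNAi). Among the 64 reporter probe sets, which detect marker genes used in plant transformation, 2 were bright. The first read 3.12 and 2.97 on the wild-type arrays, 13.96 and 14.41 in overexpression and 13.40 and 12.91 in RNAi. Counted from the floor of log2 5, it was higher than in wild type by at least 9.19 on the log2 scale in overexpression (adjusted p = 0.0338) and by at least 8.16 in RNAi (adjusted p = 0.0262). Without any 1 of the 6 arrays, with 2 residual degrees of freedom left, its adjusted p ran from 0.251 to 0.303 for overexpression and from 0.195 to 0.286 for RNAi. The second read 5.15 and 3.50 in wild type, 3.59 and 5.09 in overexpression and 13.22 and 13.64 in RNAi (RNAi against wild type at least 8.43 higher, counted from the floor; adjusted p = 0.124, intensity-trend adjusted p = 0.00233). The other 62 reporter probe sets stayed at or below 7.03 on every array.

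**Figure D3:**
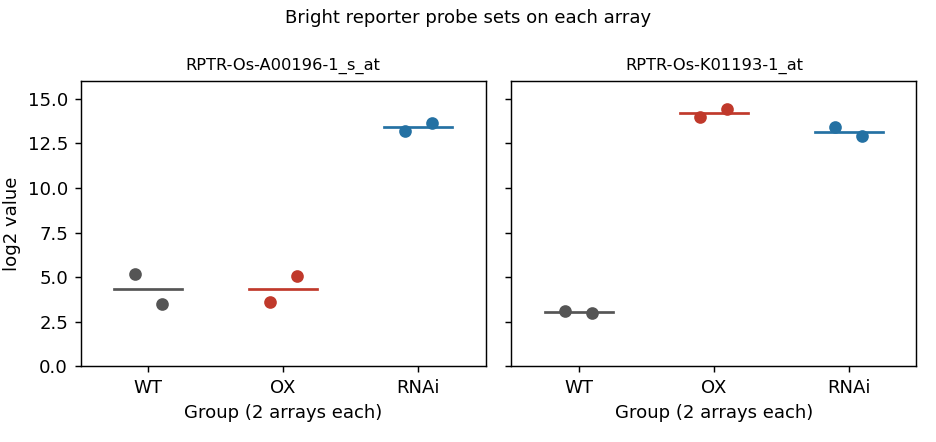
Log2 values of the 2 bright reporter probe sets on each of the 6 arrays, with a dot per array and a line at the mean of each group of 2. The first reporter probe set (right panel) reads 12.91 or more on the 4 transgenic arrays and 3.12 or less on the wild-type arrays; the second (left panel) reads 13.22 or more on the RNAi arrays alone.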

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

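All tests in this part were chosen after the patterns they weigh had been seen, and those of a wrong label, RNA degradation, dividing cells and shared wild-type arrays after their own results had been seen too.

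Signals appeared in reporter probe sets, which the gene comparisons leave out. On the first reporter probe set the lowest overexpression array exceeded the highest wild-type array by 10.84 on the log2 scale and the lowest RNAi array did so by 9.79; on the second, the lowest RNAi array did so by 8.07, while overexpression and wild type overlapped. Both wild-type arrays of the first lay under the filter's floor of log2 5, from which these first gaps are at least 8.96 and 7.91. Every array correlated best with the other array of its group, but the smallest margin was 0.00195 (SD over the arrays 0.00791), so a wrong label cannot be told apart from a difference between the plants by this test. The reporters themselves argue against 1 array swapped between groups. The first read 3.12 and 2.97 in wild type, 13.96 and 14.41 in overexpression and 13.40 and 12.91 in RNAi. The second read 3.59 and 5.09 in overexpression and 13.22 and 13.64 in RNAi. A swap of both arrays of 1 group with both of another is not addressed by these values. A marker gene carried by the transformation constructs is a candidate explanation that was not tested, since the constructs are not described in the labels.

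The cellulose synthase and kinesin lists were lower in RNAi than in wild type and higher in overexpression than in RNAi by camera, but not with an estimated correlation (adjusted p = 0.5998 and 0.675 with an estimated correlation); against wild type, overexpression was past the threshold for kinesins (adjusted p = 0.0181, but adjusted p = 0.887 with an estimated correlation) and not for the cellulose synthase list (adjusted p = 0.0510). For the cellulose synthase list between overexpression and RNAi, array scaling is argued against by a median of 0.93 after quantile normalisation (SD over members of the move 0.0707). A single array is argued against there by a lowest median of 1.003 over the 6 fits that leave out 1 array. Leaving out a wild-type array cannot change that median, so only the fits without an overexpression or RNAi array bear on it. For the kinesin call of overexpression against wild type a single array stays open, since that call ended without wild-type replicate 2 or overexpression replicate 1. RNA degradation is argued against by the 3' minus 5' difference of 4 control genes, which was larger in RNAi than in overexpression by only 0.0356 (SD over the genes 0.144). A difference in dividing cells cannot be told apart from a change within cells by the test used. It set the upper quartile of the cell cycle and replication list, 0.84, beside the kinesin median of 1.02. These are unlike measures, since even a list centred on 0 has an upper quartile above 0. On like measures the medians were 0.06 for the cell cycle and replication list, whose members went both ways, and 1.02 for kinesins. The difference in OsUBA transcript that the groups are named for remains an open explanation, untested here because only 1 overexpression group and 1 RNAi group were measured, without their target's level.

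The log2 changes of the 2 transgenic groups against wild type were positively correlated. Shared wild-type arrays may account for this: the covariance was 1.04 times that simulated for unchanged groups that share them, a test that could have come out higher or lower. The correlation was 0.273 against 0.499 in those simulations, and 55.6% against 66.6% of probe sets had the same sign. Both of these measures also fall where each group has changes of its own, which the simulated unchanged groups lack. They therefore cannot decide whether the shared arrays account for the correlation. The covariance itself was 0.254 against a simulated 0.245 (SD over simulations 0.00495). A covariance near the simulated one does not show that the 2 groups share no changes, so it alone does not settle the question. No biological explanation was tested.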

How the results depend on the processing

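Quantile normalisation and median centring of the gene lists were chosen after the data were seen. So was every alternative to the intensity-trend counts, to the genes named by that fit and to the reporter fit. The other tests were planned. No called gene, list or reporter changed sign under any alternative run. Signal over background limits what dim probe sets can show, since no detection calls were used and replicates spread most at low values. The cause of the moves was not tested, except that fits with 4 arrays or 1 array less have fewer residual degrees of freedom.

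Without a trend, overexpression against wild type (0 calls) gave 1 with a mean of log2 5 or more, 16 with 2 arrays at log2 6 or more, 6 with averaged probe sets, 2530 at a 2-fold change with unadjusted p under 0.05, and 144 with the trend. RNAi against wild type (1 call) gave 0 with no filter, 18, 20, 4, 2933 and 313 under those settings, 0 with only 4 arrays, and 0 to 0 without 1 array. Overexpression against RNAi (5 calls) gave 0 with no filter, 449, 593, 480, 4312 and 1725, then 94 with array weights, 0 with only 4 arrays and 0 to 0 without 1 array. Under quantile normalisation it gave 11 (81.8% higher) and under centring 8 (87.5% higher), against 100% of the 5. With replicate number as a replicate block, the no-trend counts were 0, 0 and 0, and the intensity-trend counts 109, 393 and 1595; the pairing check gave correlations of same-numbered deviations of 0.0365, -0.0331 and -0.00984, so the numbers do not pair the arrays.

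With the intensity trend, overexpression against wild type (144) gave 219 under centring, 255 with only 4 arrays, 93 with averaged probe sets, 2093 at 2-fold and unadjusted p under 0.05, 0 without the trend, and 0 to 223 without 1 array. RNAi against wild type (313) gave 141 with 4 arrays, 143 with averaged probe sets, 2694 at 2-fold, 1 without the trend, and 16 to 716 without 1 array. Overexpression against RNAi (1725) gave 4064 at 2-fold, 5 without the trend, and 276 to 1830 without 1 array. Opposite calls (22) ran from 0 to 61 without 1 array; calls in the same direction (16) were 26 under centring and 0 to 17 without 1 array.

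Lists past the threshold (2, 8 and 7) were 0, 0 and 0 with an estimated correlation; fry gave 0, 1 (phenylpropanoid, adjusted p = 0.0353) and 7, and averaged probe sets gave 1 for overexpression against wild type. The 7 of fry were not the 7 of camera: the shorter auxin, broader auxin and jasmonate lists did not pass it (adjusted p = 0.0662, 0.119 and 0.154), and redox enzyme, brassinosteroid and clock and flowering lists did (0.0125, 0.0320 and 0.0320). Without 1 array they ran from 0 to 4, 5 to 9 and 6 to 9. The cellulose synthase, kinesin, shorter auxin and phenylpropanoid lists passed under every scaling, block and left-out array in both comparisons with RNAi plants. Of 204 values of single lists, 157 stayed on their side of the threshold and 47 became weaker. For named genes with the trend, 1182 of 1644 stayed, 457 became weaker and 5 stronger; without it, 173 of 231 stayed, 45 became weaker and 13 stronger. Without 1 array the fold moved by over 1.5 times in 2 of 24, 8 of 40 and 16 of 41 of the named calls of the intensity-trend fit, locus-only genes included. For the reporters, 44 of 60 stayed, 14 became weaker and 2 stronger.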

Other observations

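Several other gene groups missed the threshold of the set test between overexpression and RNAi. Of 5 circadian clock genes, 5 had a negative log2 change and 0 passed adjusted over the list alone (median -0.65, camera adjusted p = 0.0553). Of 21 expansins, which loosen cell walls, 15 had a positive change and 3 passed adjusted over the list alone (median 0.73, camera adjusted p = 0.0564). Of 6 WRKY genes 0 had a positive change and 0 passed adjusted over the list alone (median -0.39, camera adjusted p = 0.173). Of 16 brassinosteroid genes, 11 had a positive change and 2 passed adjusted over the list alone (camera adjusted p = 0.149). With an estimated correlation 0 of 45 lists passed.

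Of 24 aquaporins, water channels of membranes, 2 were higher and 1 lower in overexpression than in RNAi, adjusted over the list alone (median -0.06, camera adjusted p = 0.936). Fry's test for change in either direction passed for 33 of 45 lists in that comparison, the aquaporins among them (adjusted p = 5.88e-05). Photosynthesis genes (18 genes, median -0.12), heat shock proteins (22 genes, median -0.04) and ubiquitin system genes (36 genes, median -0.06) did not pass camera in that comparison (adjusted p = 0.625, 0.799 and 0.799). Root, seed and senescence marker lists did not pass either (adjusted p = 0.625, 0.670 and 0.670).

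Groups did not overlap in 41.7% of probe sets between overexpression and wild type, 40.9% between RNAi and wild type and 51.4% between overexpression and RNAi, where chance gives 33.3%. The mean 3' minus 5' difference of 4 control genes ran from 1.64 to 1.89 over the 6 arrays.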
